A study of Homo sapiens with 8 samples.

How the data were processed

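RNA was sequenced from 8 samples of U937 cells, in 4 groups of 2 (AML1/ETO clone 9/14/18 or LacZ clone 9/10/7, with ponasterone A or ethanol). Per the labels' protocols, RNA was extracted with an RNeasy Plus Micro kit, and the library wording names both a TruSeq stranded mRNA kit and a Ribo-Zero Plus kit. Per the submitters' processing notes, the tools were FastQC, MultiQC, cutadapt 3.7, STAR 2.7.8a, featureCounts 2.0.1 and DESeq 2.11.40.7, with hg38 as the genome. The notes give no role for each tool, and the annotation release, the strand setting and the handling of reads with several positions are not given in the sources used here. The deposited values are a signal per gene and sample that the authors made by dividing gene counts by 1 factor per sample, that is, normalized counts. That unit was tested on the file: for each sample a single value of 1 read was found, and 100% of its values were whole multiples of it within 0.001 of a read. Size factors recomputed from these reads by the DESeq2 method equalled those in the file.

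The table holds 58051 Ensembl genes in 8 sample columns. GENCODE release 29 on GRCh38 matched 57447 of them (99.0%) and gave positions, and symbols were available for 42422 (73.1%). All 37 mitochondrial genes had 0 reads, so mitochondrial content could not be used as a sign of RNA quality. Library depth, as recovered reads, ran from 21696799 to 33082585. Depth limits cover counting error only. Reads without molecular identifiers are not independent molecules, and the spread between the 2 samples of a group is larger than counting error. Within groups, chi-squared per degree of freedom was 17.1 and 28.8 for LacZ, with ethanol and with ponasterone A. For AML1/ETO it was 9.78 and 12.9.

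The main test was limma 3.58.1 in R 4.3.3 on log2(deposited value + 1), with a variance trend, over genes with a mean of at least 10 across the 8 samples (15014 genes). One model of 4 groups gave all comparisons, with 4 residual degrees of freedom and a prior of 5.81. Tests were two-sided, and adjusted p is the Benjamini-Hochberg value with a threshold of 0.05. The comparisons were induction in the AML1/ETO clone, ponasterone A in the LacZ clone, the difference of these effects as an interaction term, and the clone difference under ethanol and under ponasterone A. Of 39 gene lists written down from general knowledge, 34 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over the lists, and members were also adjusted over the list alone. Comparisons, tests, the main filter, the lists, the naming rule and the alternatives, except those named as added, were chosen before the data were examined, when the file was assumed from its name to hold normalized counts, which it did.

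Genes were named by a rule. For induction, LacZ, the difference and the clone difference under ethanol these were the 10 largest rises and 10 largest falls among genes with a symbol, a mean of at least 50, an adjusted p under 0.05 and, for comparisons of 2 groups, no overlap of the groups' values. RUNX1 was named throughout, and a fitted change of RUNX1T1 is given for induction. RUNX1T1 had 2 reads in the 4 LacZ libraries together, so for the other comparisons its values stand in place of a fitted change. Up to 4 members with the smallest p were named from each list described. The clone difference under ponasterone A is given as counts and genes named elsewhere. CYP1A1 and the one-clone genes beyond the rule were chosen after their values were seen. For genes with 0 to 3 reads in a group the fitted change depends on the added 1, so their values are given, and a fitted change printed for them measures no exact fold.

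Alternatives were another added value, another filter or none, libraries scaled to equal totals, quantile normalization, only the groups compared, a robust variance prior, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, a replicate block, a minimum change and leaving out each library in turn. Corrections for GC content (lowess, span 0.3, GC known for 99.6% of tested genes) and for GC content and length, and the joint removal of LacZ_EtOH replicate 1 and LacZ_PonA replicate 2, were added after seeing the data. On the recovered reads edgeR called 7467 genes on induction, 4534 in the LacZ clone, 1555 for the difference, 3675 between clones under ethanol and 5601 under ponasterone A. DESeq2 called 6762, 4509, 1384, 3121 and 5015. The pipeline was tested on simulated data with known changes: limma recovered 76.1% of 2-fold changes on induction, 77.6% in the LacZ clone, 49.3% for the difference, 73.1% between clones under ethanol and 79.1% under ponasterone A. Among unchanged simulated genes it called between 4 and 14 per comparison, with 0 calls of the wrong sign. In this simulation genes varied independently of one another, with no gradient shared across genes. It therefore does not measure false calls that such a gradient among the real libraries would cause. No sample was left out of the main test.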

Results

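RNA sequencing measured transcripts in 8 samples of U937 cells, a human line derived from a histiocytic lymphoma and used as a model of monocytic cells. The samples came from 2 clones. Clone 9/14/18 carries inducible AML1/ETO, the fusion of RUNX1 (AML1) with RUNX1T1 (ETO) found in acute myeloid leukemia, and clone 9/10/7 carries LacZ as its control. Each clone received ponasterone A, an ecdysteroid used to switch on the transgene, or ethanol, the vehicle. Each of the 4 groups held 2 samples, so every group value is a mean ± SD of normalized counts with n = 2. In sample names AE stands for the AML1/ETO clone, EtOH for ethanol and PonA for ponasterone A. Coordinates are on GRCh38 (hg38). Recovered reads per library came to 33082585 and 31220370 in the LacZ clone with ethanol and 27636944 and 25441716 in the LacZ clone with ponasterone A. In the AML1/ETO clone they came to 25425667 and 30361389 with ethanol and 21696799 and 25688418 with ponasterone A. Between 22857 and 24403 genes had reads in a library, and 15014 genes passed the filter and were tested. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples.

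The first question was whether the fusion's sequences were read in the clone said to carry it. RUNX1T1 (ENSG00000079102, chromosome 8, 91954967 to 92103286), the ETO part, gave 2 reads in all 4 LacZ libraries together. Its reads can come from its own gene or from the fusion, which gene counts do not separate. In the AML1/ETO clone RUNX1T1 stood at 711 ± 28.5 with ethanol, the uninduced state, and at 1115 ± 255 with ponasterone A. That rise had a log2 fold change of 0.63 (SE 0.24, adjusted p = 0.0479). RUNX1 (ENSG00000159216, chromosome 21, 34787801 to 36004667), a regulator of blood cell development whose reads can come from its own gene or from the AML1 part, rose from 444 ± 0.327 to 690.3 ± 171 in the AML1/ETO clone (0.61, adjusted p = 0.00953). In the LacZ clone RUNX1 fell from 701 ± 92.8 to 505 ± 26.7 (-0.47, adjusted p = 0.0486). The difference between the clones in the RUNX1 response was 1.08 (adjusted p = 0.0145).

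These calls rest on few libraries. The RUNX1T1 rise no longer passed without AE_EtOH replicate 1 (0.59), AE_EtOH replicate 2 (0.67), AE_PonA replicate 1 (0.87) or AE_PonA replicate 2 (0.40). The RUNX1 rise no longer passed without AE_EtOH replicate 1 (adjusted p = 0.0541), AE_EtOH replicate 2 (0.0545) or AE_PonA replicate 2 (0.0747). The RUNX1 fall in the LacZ clone no longer passed without LacZ_EtOH replicate 1 (-0.33), LacZ_PonA replicate 1 (-0.41), LacZ_PonA replicate 2 (-0.52), AE_EtOH replicate 1 or AE_EtOH replicate 2 (-0.47 in both). The RUNX1 difference no longer passed without LacZ_EtOH replicate 1 (0.94), AE_EtOH replicate 1 or AE_EtOH replicate 2 (1.08 in both).

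**Figure D1:**
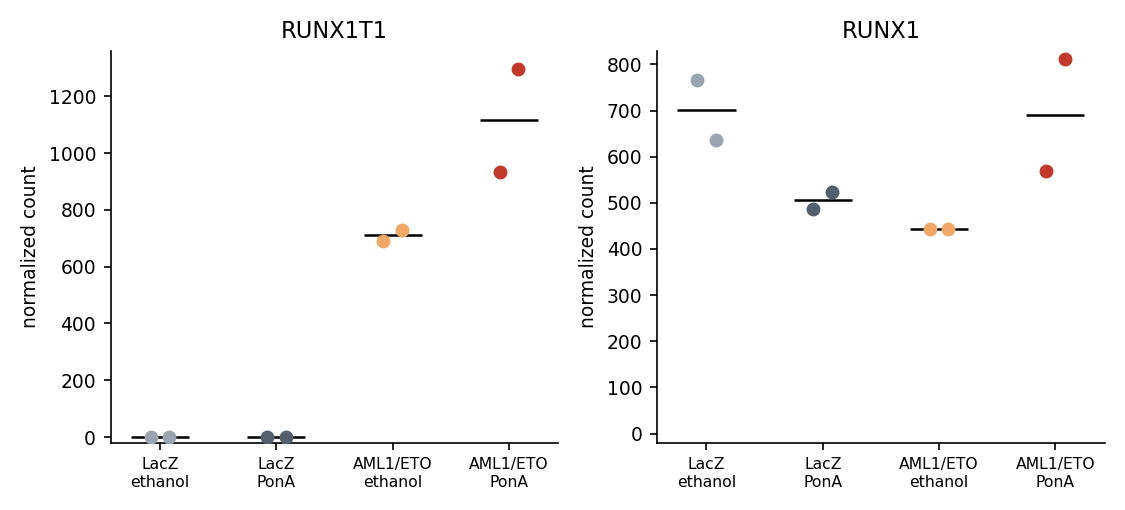
Normalized counts of RUNX1T1 and RUNX1 in each of the 8 libraries, by group, with points for libraries and bars for group means. RUNX1T1 lies at 690, 731, 934 and 1296 in the AML1/ETO clone and near 0 in the 4 LacZ libraries.

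Libraries also differed along GC content, in step with treatment. The median deviation from each gene's mean, top GC quartile minus bottom, was 0.31 and 0.14 for LacZ with ethanol and 0.15 and 0.26 for AML1/ETO with ethanol. It was -0.06 and -0.37 for LacZ with ponasterone A and -0.24 and -0.16 for AML1/ETO with ponasterone A. The median log2 fold change went from 0.20 in the lowest GC quartile to -0.19 in the highest on induction, and from 0.22 to -0.22 in the LacZ clone. Among markers of other cell types, a mean of at least 10 was reached by 2 of 16 erythroid, 5 of 16 megakaryocyte, 7 of 13 B cell, 3 of 19 T and NK cell and 3 of 16 epithelial and fibroblast genes. The B cell and megakaryocyte lists, the only ones of these with enough members to test, did not pass by camera in any of the 5 comparisons. By fry the B cell list passed in all 5, in both directions, and the megakaryocyte list in 3. Summed B cell values were 577 and 425 in the LacZ clone and 550.3 and 1043 in the AML1/ETO clone, with ethanol and ponasterone A in that order. Of 14 mast cell and basophil genes 3 reached that mean, and their summed values were 4154 and 2508 in the LacZ clone and 15604 and 5160.4 in the AML1/ETO clone, with ethanol and ponasterone A in that order. The tryptase gene TPSAB1 alone had a mean of 6782 over the 8 libraries.

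**Figure D2:**
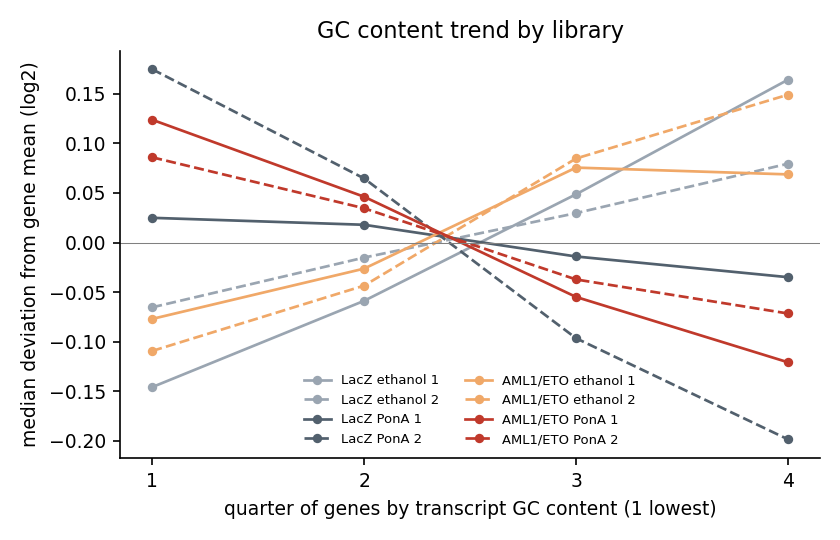
Median deviation of log2 values from each gene's mean over the libraries, by quartile of gene GC content, 1 line per library. Lines of the 4 ethanol libraries rise with GC content and those of the 4 ponasterone A libraries fall, most for LacZ_PonA replicate 2 (-0.37 between the end quartiles).

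Induction in the AML1/ETO clone, ponasterone A against ethanol, asks which genes change when the inducer is given to the clone with the fusion. It is the main comparison that the series describes. RUNX1T1 was already read with ethanol, so the ethanol samples cannot be taken as a state without the fusion. Whether those reads came from the fusion or from the own RUNX1T1 gene cannot be told from gene counts. The contrast also holds any effect of the inducer itself. The chemokine genes CXCL10 (chromosome 4, 76021117 to 76023497) and CXCL11 (chromosome 4, 76033682 to 76041415), whose products bind the receptor CXCR3, rose from 13.6 ± 5.67 to 4801 ± 358 and from 15.1 ± 10.2 to 4686 ± 327. Their log2 fold changes were 8.42 (SE 0.65, adjusted p = 1.48e-05) and 8.34 (SE 0.60, adjusted p = 9.49e-06). IL7R (chromosome 5, 35852695 to 35879603), which encodes the interleukin 7 receptor, rose from 4.23 ± 1.47 to 986 ± 13.6. Several genes with at most a few reads under ethanol also rose: TM4SF1 from 0.44 to 496 ± 75.9, FCRLA from 2.57 to 499 ± 26.3, CLRN3 from 0.44 to 277 ± 32.4 and PDE1C, a calmodulin-dependent phosphodiesterase gene, from 0.44 to 259.7 ± 14.6. CYP11A1 (chromosome 15, 74337759 to 74367740), which encodes the enzyme that cleaves the cholesterol side chain in the first step of steroid synthesis, went from 0 to 389 ± 52.9. The pseudogene PPIAP46 (chromosome 15, 74350768 to 74364620) lies inside CYP11A1 on the other strand and went from 0.44 to 1828 ± 9.81. The pseudogene CYP2B7P went from 0.972 to 254 ± 46.

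Among the genes that fell on induction, RPS16 (chromosome 19, 39433207 to 39435948), which encodes a protein of the small ribosomal subunit, went from 9362 ± 1130.2 to 600.2 ± 51.1 (-3.96, SE 0.31, adjusted p = 1.57e-05). RPLP1 (chromosome 15, 69452784 to 69456194), which encodes an acidic protein of the large subunit, went from 46579.6 ± 1287 to 6549.9 ± 1258 (-2.84, adjusted p = 3.67e-05). CIITA (chromosome 16, 10866222 to 10943021), the master activator of MHC class II genes, fell from 361 ± 10.3 to 51.7 ± 0.681. PDYN (chromosome 20, 1978757 to 1994285), which encodes the precursor of dynorphin opioid peptides, fell from 508 ± 19.1 to 80.7 ± 12.5 (-2.65, adjusted p = 9.50e-07). RIN3, which encodes an exchange factor for RAB5, fell from 1901 ± 21 to 228 ± 59.5, and BHLHE40, which encodes a repressor tied to the circadian clock, from 2096 ± 159.8 to 417 ± 89. ACTMAP, which encodes an actin-maturing protease, fell from 222 ± 21.6 to 35.1 ± 4.26. The antisense genes IGFL2-AS1 and ZNF710-AS1 fell from 106 ± 15 to 10.8 ± 0.137 and from 409 ± 33.2 to 80.6 ± 13.8, and the laminin pseudogene LAMB2P1 from 84.5 ± 11.1 to 16.3 ± 1.51. In the LacZ clone RIN3 (-1.31), CIITA (-0.99), ACTMAP (-1.54), BHLHE40 (-0.87), ZNF710-AS1 (-1.43) and LAMB2P1 (-0.91) were also called lower. RPS16 and RPLP1 were as well, while IGFL2-AS1 (-0.21) and PDYN (-0.00038) were not. By the limma interaction test RPS16 (adjusted p = 0.503), RPLP1 (0.317), ACTMAP (0.0624) and ZNF710-AS1 (0.0664) did not differ between the clones. The strand setting and the handling of reads with several positions are not given in the sources used here. Values of antisense and overlapping genes, of pseudogenes and of genes with close copies (FCGR2B, the HLA-DRB genes, ribosomal protein and histone genes) are therefore uncertain.

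Of 30 tested interferon-stimulated genes, 22 rose and 3 fell on induction, with a median log2 fold change of 1.89 (adjusted p = 4.05e-07 by camera; adjusted p = 0.0995 with an estimated correlation). OAS1, an antiviral sensor of double-stranded RNA, rose from 68 ± 1.64 to 919 ± 33.6 (3.74), IFIT1 from 103 ± 0.838 to 979 ± 116 (3.24), IFIT2 from 53.2 ± 3.05 to 468 ± 15.1 and SAMD9 from 714 ± 17.9 to 2432 ± 2.2. Of 25 inflammatory and NF-kB response genes, 16 rose and 2 fell, with a median of 0.87 (adjusted p = 6.70e-05; adjusted p = 0.232 with an estimated correlation). IL1B, which encodes interleukin 1 beta, rose from 61.2 ± 0.725 to 709 ± 7.84, the neutrophil chemokine gene CXCL8 from 1034 ± 107 to 16304 ± 2174, FOS from 88.1 ± 0.255 to 639 ± 83.3 and CD83 from 472 ± 5.45 to 1294 ± 8.95. Of 23 monocyte and macrophage genes, 12 rose and 4 fell (median 0.72, adjusted p = 0.0158; adjusted p = 0.232 with an estimated correlation). The scavenger receptor gene CD36 rose from 764 ± 29.1 to 9746 ± 687, FCGR2B from 97 ± 17.8 to 1284 ± 57.5, TLR4 from 713 ± 20.2 to 1752 ± 76.8 and TLR2 from 119 ± 4.44 to 463 ± 34.8. Of 30 apoptosis regulators, 17 rose and 5 fell (median 0.38, adjusted p = 0.0158; adjusted p = 0.374 with an estimated correlation). The antiapoptotic MCL1 rose from 4675 ± 136 to 17519 ± 56.6, the proapoptotic BAK1 from 1319 ± 25.9 to 2334 ± 153 and PMAIP1 from 521 ± 6.61 to 1079 ± 7.5, while the proapoptotic BBC3 fell from 413 ± 42.6 to 187 ± 15.2.

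Of 22 cholesterol synthesis genes, 17 fell and 1 rose, with a median of -0.63 (adjusted p = 2.24e-05; adjusted p = 0.102 with an estimated correlation). INSIG1, a sensor of sterols, fell from 32110.0 ± 1323 to 16893 ± 630.2, SREBF2, the activator of this pathway, from 3001 ± 62.1 to 1519 ± 158, FDFT1 from 21109.8 ± 125 to 12609.5 ± 196 and MVK from 923 ± 23.8 to 494 ± 25.6. Of 20 genes reported as repressed by AML1/ETO, 10 fell and 3 rose (median -0.47, adjusted p = 0.0180; adjusted p = 0.562 with an estimated correlation). LAT2 fell from 3422 ± 24.7 to 1741 ± 92.2, RUNX3 from 787 ± 29.2 to 255 ± 44.6 and SPI1, which encodes the myeloid factor PU.1, from 939.9 ± 68.5 to 453 ± 28.6, while ID1 rose from 73.7 ± 1.05 to 226 ± 3.81. Of 14 genes reported as activated by AML1/ETO, 4 rose and 5 fell, and the list did not pass (adjusted p = 0.804). Within it CDKN1A, a cell cycle inhibitor gene, rose from 368 ± 18 to 1942 ± 28 and CSF3R fell from 1625 ± 118 to 755 ± 67.4. Of 17 primary granule genes, 3 rose and 6 fell, and the list did not pass (adjusted p = 0.123). Its members AZU1, BPI and ELANE, which encode antimicrobial granule proteins, fell from 6947 ± 394 to 1819 ± 49.2, from 162 ± 14.3 to 35.1 ± 4.26 and from 5159 ± 454 to 1717 ± 413.

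Epigenetic modifiers are the subject named in the series title. Of 36 histone methyltransferases, 20 fell and 6 rose on induction (median -0.38, adjusted p = 0.0299; adjusted p = 0.854 with an estimated correlation). EHMT2, which encodes the H3K9 methyltransferase G9a, fell from 2690.3 ± 97.7 to 1549.8 ± 68.7 and SETD5 from 2755 ± 89.7 to 1568 ± 189, while SUV39H2 rose from 820.1 ± 39.3 to 1340.3 ± 80.1 and PRMT1 from 5337 ± 58.2 to 8113 ± 547. Of 50 Polycomb, chromatin reader and remodeller genes, 19 fell and 6 rose (median -0.23, adjusted p = 0.0299; adjusted p = 0.854 with an estimated correlation). RNF2, a Polycomb ubiquitin ligase gene, rose from 835 ± 6.32 to 1757 ± 209.9, while CBX7 fell from 611 ± 35.1 to 295 ± 18.4 and SMARCA2 from 3508 ± 153 to 1844 ± 114. Without AE_PonA replicate 1 the adjusted p of these lists was 0.0779 and 0.0697, and with GC content corrected the second stood at 0.0530. Histone demethylases (2 rose and 9 fell of 23, adjusted p = 0.158), histone acetyltransferases and deacetylases (3 and 13 of 28, adjusted p = 0.0801) and DNA methylation enzymes (3 and 5 of 15, adjusted p = 0.578) did not pass. HDAC1, among the second of these, rose from 5667 ± 3.72 to 9372 ± 369.

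By the limma test, 7589 of 15014 genes changed on induction, 3856 higher and 3733 lower. Of these, 730 rose and 1041 fell at least 2-fold on the log2(value + 1) scale, and 223 rose and 67 fell at least 4-fold. Adjusted over the list alone, the members called higher and lower were 22 and 4 for interferon-stimulated genes, 16 and 2 for inflammatory genes, 12 and 4 for monocyte genes, 18 and 5 for apoptosis regulators and 1 and 18 for cholesterol synthesis. For the genes reported as repressed, the methyltransferases and the Polycomb list they were 3 and 10, 8 and 22, and 6 and 19. The count was 5010 without AE_EtOH replicate 2 and 5015 without AE_PonA replicate 1. The monocyte list no longer passed among genes with a mean of at least 50 (adjusted p = 0.111), and 7 of the 8 lists passed with GC content corrected.

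**Figure D3:**
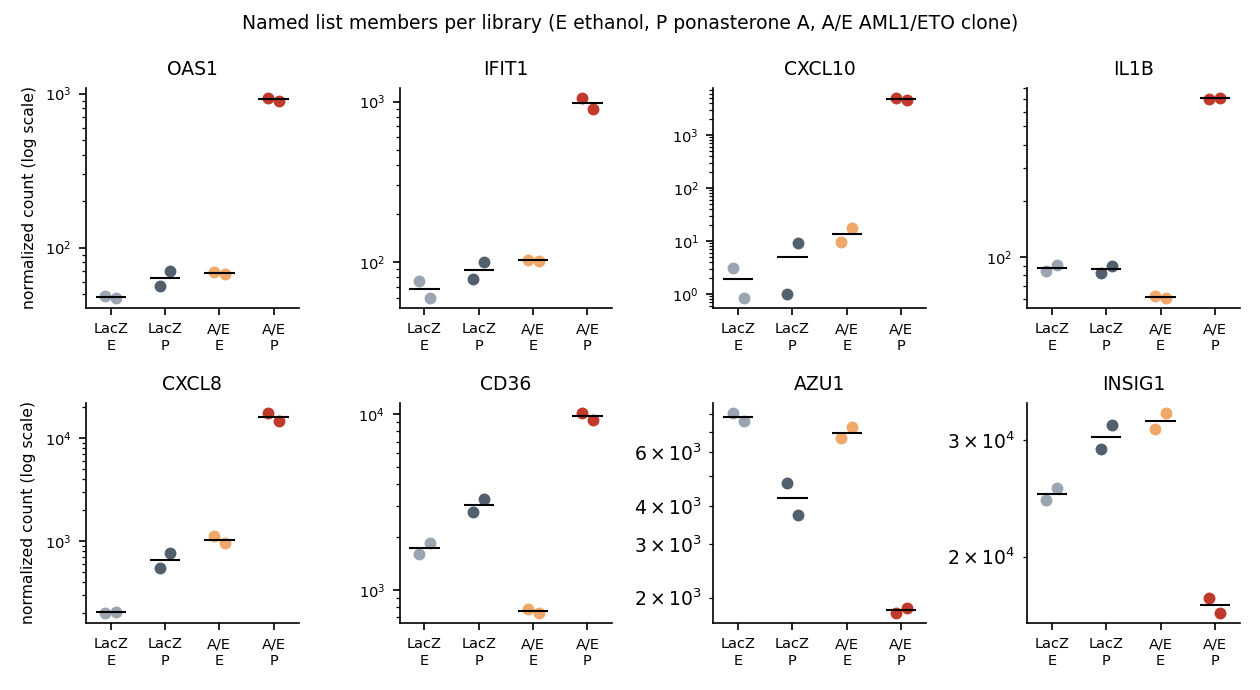
Normalized counts on a log axis of OAS1, IFIT1, CXCL10, IL1B, CXCL8, CD36, AZU1 and INSIG1, with points for the 8 libraries by group and bars for group means. OAS1 moves from 68 to 919 and CXCL10 from 13.6 to 4801 in the AML1/ETO clone, while AZU1 and INSIG1 fall there.

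Ponasterone A in the LacZ clone against ethanol asks what the inducer does where there is no AML1/ETO. RPS16 fell from 12268 ± 6661 to 1072 ± 298 (-3.43, adjusted p = 0.00674) and RPLP1 from 48019 ± 2115 to 11044 ± 5257 (-2.21). HNRNPH3, an RNA-binding protein gene, fell from 1989.6 ± 911 to 483 ± 66.5. BCL2L12 fell from 856 ± 150.4 to 263 ± 155, PRKCSH from 6065 ± 1437 to 1849 ± 732, the splicing factor gene SF3A1 from 2447 ± 593 to 750.4 ± 191 and ARHGDIA from 2260.0 ± 657 to 693 ± 194. FAM222B and CNOT3 fell from 101 ± 33 to 33.1 ± 18.1 and from 342 ± 85.9 to 107 ± 12.8. The chemokine gene CXCL8 rose from 203 ± 4.04 to 660.2 ± 155 (1.67, SE 0.15, adjusted p = 0.00674), the collagenase gene MMP1 from 113 ± 16.9 to 229 ± 51.2 and FABP4, a fatty acid carrier gene, from 14 ± 0.488 to 39.7 ± 18.8. LINC02207 went from 22.4 ± 11.3 to 46.4 ± 17.3 (1.06), a call lost with edgeR (adjusted p = 0.0511), with GC content corrected (0.0583), with no filter (0.0755) and without LacZ_EtOH replicate 1 (0.55, adjusted p = 0.295). The other 6 named rises rested on group means under 10: PDE1C (0 to 3.79), FAM83G (0 to 3.49), FCRLA (0.379 to 3.79), CYP11A1 (0 to 2.1), HLA-DRA (2.82 to 8.26) and PRODHLP (2.44 to 6.31). None of these 6 calls held throughout. With edgeR and DESeq2 those of FCRLA, CYP11A1, HLA-DRA and PRODHLP were lost (adjusted p = 0.0518 to 0.187 and 0.0520 to 0.147), and with an added 5 all but that of HLA-DRA (0.0572 to 0.138).

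Of 32 cytosolic ribosomal protein genes, 21 rose and 2 fell in the LacZ clone (median 0.44, adjusted p = 5.16e-05). RPL6 rose from 25091 ± 1512 to 35445 ± 4305 and RPS6 from 47911 ± 6358 to 70435 ± 10524. Of 30 mitosis genes, 17 rose and 3 fell (median 0.28, adjusted p = 0.000366), with CCNB1, which encodes cyclin B1, at 6048 ± 451 and 8553 ± 964 and TPX2, a spindle factor gene that fell, at 11275 ± 626 and 6431 ± 1424. Of 13 replication-dependent histone genes, 6 rose and 0 fell (median 0.47, adjusted p = 0.000683), with H1-3 at 7998 ± 1258 and 12091 ± 2167. Of 50 Polycomb, reader and remodeller genes, 20 fell and 4 rose (median -0.33, adjusted p = 5.31e-05), with MEN1, a partner of MLL methyltransferases, going from 568 ± 33.4 to 274 ± 55.1 and CHD2 from 2507 ± 292 to 1504 ± 183. Of 36 histone methyltransferases, 15 fell and 3 rose (median -0.26, adjusted p = 0.00769), with DOT1L, the H3K79 methyltransferase gene, falling from 1896 ± 469 to 923 ± 199. Of 23 histone demethylases, 9 fell and 0 rose (adjusted p = 0.0186), with PHF8 going from 1253 ± 12.8 to 655 ± 173. Of 28 acetyltransferases and deacetylases, 11 fell and 1 rose (adjusted p = 0.0186), with CREBBP, an acetyltransferase gene, going from 565 ± 75.3 to 359 ± 21.4. Each of these 7 lists had adjusted p = 0.635 with an estimated correlation. Adjusted over the list alone, the members called higher and lower were 27 and 2, 20 and 3, 12 and 0, 4 and 27, 4 and 16, 1 and 10, and 2 and 11, in that order. Of 30 interferon-stimulated genes, 1 rose and 5 fell, and the list did not pass (adjusted p = 0.857).

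By the limma test, 4708 of 15014 genes changed in the LacZ clone, 2381 higher and 2327 lower, with 34 rising and 357 falling at least 2-fold. With only the 2 LacZ groups in the model, limma called 0 genes, with 5283 at an unadjusted p under 0.05, while edgeR and DESeq2 on all 8 libraries called 4534 and 4509. By chi-squared the LacZ replicates lay further apart than the AML1/ETO replicates, and the main model shared 1 spread per gene over both clones. Without LacZ_EtOH replicate 1 the count was 1, the RPS16 fall (-2.85), so each other gene call named for this clone was lost. In that setting log2 fold changes stood at 1.65 for CXCL8, 1.33 for FABP4 (0.87 without LacZ_PonA replicate 2) and -2.16 for RPLP1. Some others shrank, such as HNRNPH3 (-1.97 to -1.48) and PRODHLP (1.14 to 0.74). Among the genes with group means under 10, PDE1C (2.15), FAM83G (1.93) and CYP11A1 (1.63) did not move, and FCRLA went from 1.74 to 2.15. Without LacZ_PonA replicate 2 it was 1260, without AE_EtOH replicate 1 2990, without AE_EtOH replicate 2 2996, and with LacZ_EtOH replicate 1 and LacZ_PonA replicate 2 both left out it was 1, again RPS16. The histone gene call ended in that last setting (adjusted p = 0.217), the acetyltransferase and deacetylase call, 1 of the 7, with GC content corrected (0.144) and the ribosomal protein call after quantile normalization (0.0543). Libraries scaled to equal totals moved the median log2 fold change of all genes from 0.02 to -0.10 and split the calls into 1234 higher and 2616 lower.

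**Figure D4:**
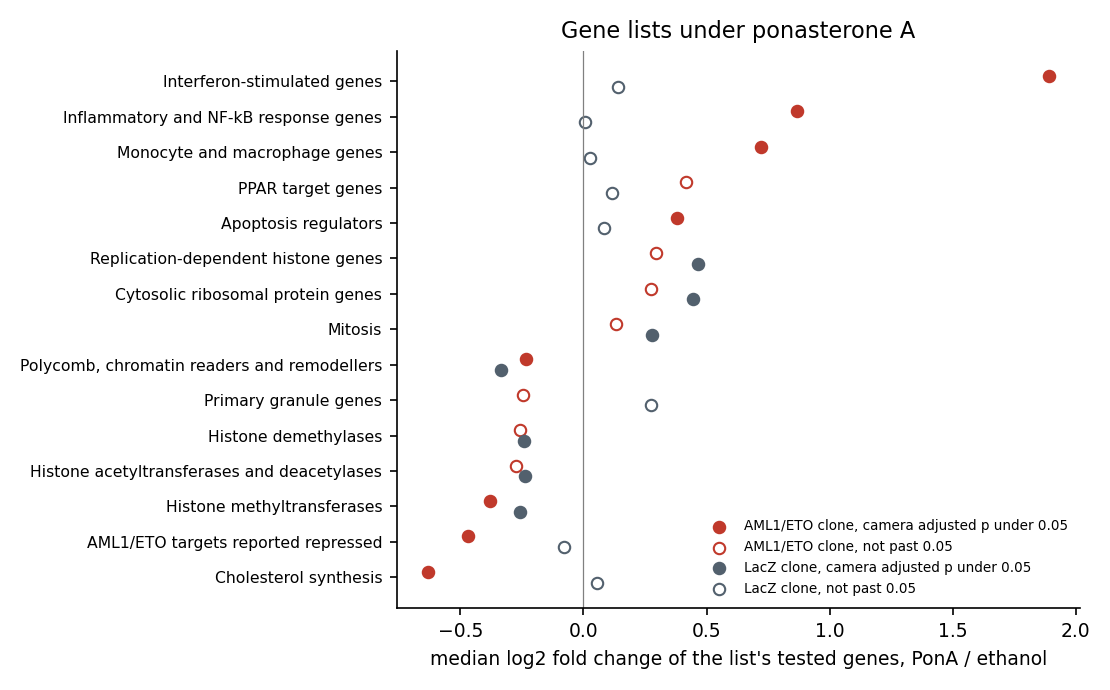
Median log2 fold change under ponasterone A of 15 gene lists in the AML1/ETO clone and in the LacZ clone, 1 point per list and clone, filled where the camera adjusted p is under 0.05. Interferon-stimulated genes have a median of 1.89 in the AML1/ETO clone and 0.14 in the LacZ clone.

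The calls of the 2 clones overlapped. Their libraries are separate, but 1 model gave both sets of calls, with a shared estimate of the spread per gene. Of the genes called higher, 1678 were shared where independent calls would share 612. Of those called lower, 1746 were shared where 579 would be. A shared spread, and the GC trend that ran with treatment in both clones, can raise the overlap above independent calls. The excess therefore does not measure a common response to the inducer. RPS16, RPLP1, CXCL8 and FABP4 were among the named genes that moved the same way in both clones. A further 94 genes were called in opposite directions, RUNX1 among them. Across genes, which are not independent replicates, the log2 fold changes of the clones had a Pearson correlation of 0.49 and a Spearman correlation of 0.59.

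The difference of the ponasterone A effects asks directly which genes answer the inducer differently in the AML1/ETO clone. Each transgene was carried by a single clone. An effect of AML1/ETO therefore cannot be told apart from any other difference between the clones in their response. Interferon-stimulated genes rose more in that clone, 20 of 30 members passing upward and 0 downward (median difference 1.84, adjusted p = 4.03e-16). This was the only list of this comparison to pass with an estimated correlation (adjusted p = 0.0213), and besides it only the same list between the clones under ponasterone A did so (adjusted p = 0.0380). OAS1 differed by 3.35, IFIT1 by 2.85 and IFIT2 by 2.64 on the log2 scale, and IFI27 read 0.972 with ethanol and 167 ± 5.51 with ponasterone A in the AML1/ETO clone. CXCL10 differed by 7.71 (SE 0.93, adjusted p = 0.000857), from 1.94 ± 1.55 and 5.0 ± 5.68 in the LacZ clone, and CXCL11 by 7.64. IL7R differed by 6.27 (adjusted p = 0.000525), against LacZ values of 5.01 ± 4.7 and 11.5 ± 0.317. SPOCD1 stood at 8.08 ± 2.86 and 9.39 ± 0.53 in the LacZ clone and at 9.35 ± 4.19 and 714 ± 11.6 in the AML1/ETO clone, and ZNF117 at 5.51, 3.72, 3.98 and 206 ± 19.4.

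Inflammatory genes also rose more in the AML1/ETO clone, 11 of 25 upward and 0 downward (median 0.76, adjusted p = 2.12e-10; adjusted p = 0.0578 with an estimated correlation). IL1B differed by 3.54, CXCL2 by 3.07, FOS by 2.83 and CXCL8 by 2.30. Among monocyte genes 10 of 23 passed upward and 1 downward (median 0.81, adjusted p = 5.04e-05; adjusted p = 0.0635 with an estimated correlation), with CD36 at 2.86, FCGR2B at 3.56, TLR2 at 1.74 and TLR4 at 1.08. Among 12 PPAR target genes 5 passed upward and 0 downward (median 0.30, adjusted p = 0.00849; adjusted p = 0.204 with an estimated correlation). PLIN2, which coats lipid droplets, went from 1183 ± 48.8 to 10957 ± 639 in the AML1/ETO clone and stood at 1084 ± 81.5 and 1492 ± 71.8 in the LacZ clone. Among apoptosis regulators 5 of 30 passed upward and 1 downward (median 0.31, adjusted p = 0.0126; adjusted p = 0.303 with an estimated correlation), with MCL1 at 2.06 and BBC3 at -1.17. Cholesterol synthesis genes differed downward, 7 of 22 passing and 0 upward (median -0.32, adjusted p = 5.79e-07; adjusted p = 0.0578 with an estimated correlation), with INSIG1 at -1.21, IDI1 at -1.20 and FDFT1 at -0.85. Primary granule genes did as well, 4 of 17 passing and 0 upward (median -0.32, adjusted p = 0.000148; adjusted p = 0.303 with an estimated correlation), with AZU1 at -1.04, CST7 at -1.13 and BPI at -1.84. Of 30 mitosis genes 0 passed singly, although the list did (median -0.14, adjusted p = 0.0136; adjusted p = 0.656 with an estimated correlation).

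Downward differences in the AML1/ETO clone included IGFL2-AS1 (-2.96), PDYN (-2.65, adjusted p = 3.28e-05), whose LacZ values were 475 ± 25 and 475 ± 16.3, and PTPN22 (-2.01), a lymphoid phosphatase gene that went from 1778 ± 56.7 to 561 ± 1.29. HLA-DRA (-2.15) went from 136 ± 4.21 to 73.7 ± 9.71 in the AML1/ETO clone (-0.88) and from 2.82 ± 0.776 to 8.26 ± 2.12 in the LacZ clone (1.27), so its fitted difference rests in part on a few reads. In the AML1/ETO clone GNRHR2 (-2.06) went from 147 ± 8.83 to 42.8 ± 18.9, LINC02908 (-2.05) from 471 ± 22.4 to 105 ± 27.1, LRRC2 (-1.95) from 544 ± 8.99 to 141 ± 11.9 and FAM9C (-1.85) from 120.3 ± 5.93 to 41.9 ± 6.91. C2orf72 stood at 230.1 ± 10.9 and 211 ± 9.49 in the LacZ clone and at 3.98 and 0 in the AML1/ETO clone, so its fitted difference rests on a few reads. Genes reported as repressed by AML1/ETO did not pass in this comparison (3 higher and 3 lower of 20, adjusted p = 0.140), and in the LacZ clone 2 of them rose and 7 fell (adjusted p = 0.221). Nor did the 4 chromatin lists: methyltransferases (adjusted p = 0.678), demethylases (0.936), acetyltransferases and deacetylases (0.936) and the Polycomb list (0.676).

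By the limma interaction test, 1546 of 15014 genes differed, 892 upward and 654 downward, of which 436 and 210 differed at least 2-fold. Adjusted over the list alone, the members called higher and lower were 22 and 2 for interferon-stimulated genes, 14 and 1 for inflammatory genes, 10 and 2 for monocyte genes, 6 and 2 for PPAR targets, 6 and 1 for apoptosis regulators, 0 and 10 for cholesterol synthesis, 0 and 6 for primary granules and 0 and 0 for mitosis. The count was 798, 788 and 2366 without LacZ_EtOH replicate 1, LacZ_EtOH replicate 2 and LacZ_PonA replicate 1, 641 and 637 without AE_EtOH replicates 1 and 2, and 858 and 891 without AE_PonA replicates 1 and 2. Calls were lost for HLA-DRA without AE_EtOH replicate 1 (-2.19) or AE_EtOH replicate 2 (-2.12), GNRHR2 without AE_EtOH replicate 1 (-1.99), C2orf72 without LacZ_EtOH replicate 1 (-2.18) or LacZ_EtOH replicate 2 (-2.09), and mitosis without LacZ_EtOH replicate 1 (adjusted p = 0.107) or LacZ_PonA replicate 2 (0.242). edgeR did not call CYP11A1, CLRN3 or C2orf72, although their log2 differences stayed large (7.44, 6.76 and -4.84). DESeq2 did not call C2orf72 either (-3.99, adjusted p = 0.0887).

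**Figure D5:**
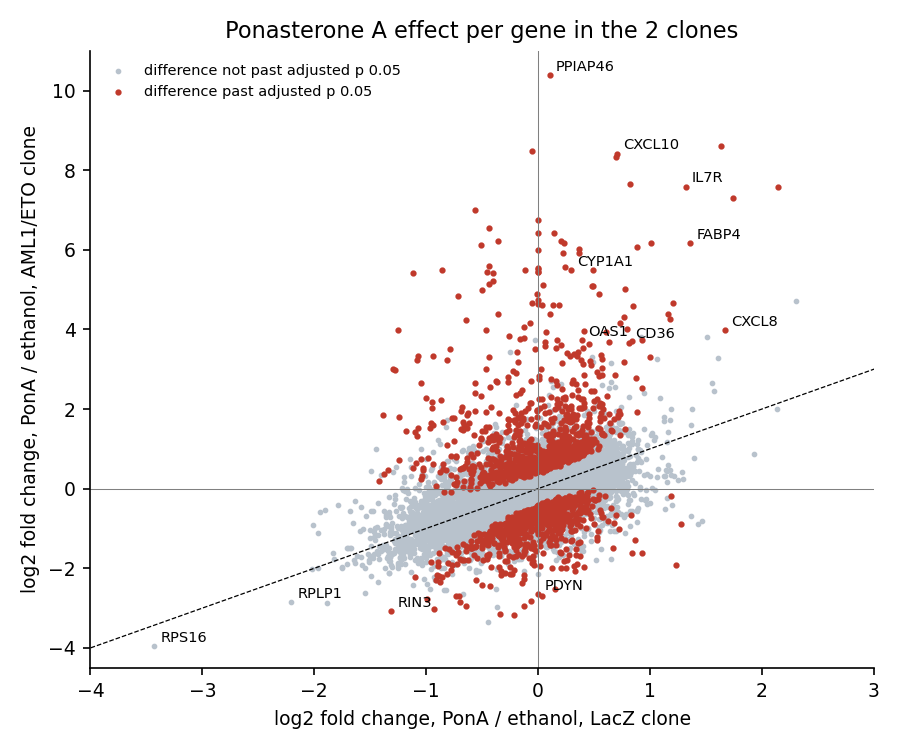
Log2 fold change under ponasterone A in the LacZ clone (x axis) and in the AML1/ETO clone (y axis), 1 point per tested gene, red where the difference passes an adjusted p of 0.05, with a dashed line of equal change. The 1546 red genes include CXCL10, at 8.42 on the y axis, while RPS16 lies at -3.43 and -3.96.

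The clone difference under ethanol asks how far the clones differed before induction. DEFB1 (chromosome 8, 6870575 to 6878022), which encodes an antimicrobial beta-defensin, stood at 11.4 ± 5.37 in the LacZ clone and 19927 ± 130.5 in the AML1/ETO clone (10.73, SE 0.24, adjusted p = 7.05e-09). F13A1, a subunit of coagulation factor XIII, stood at 2.02 and 781 ± 60.6, RASSF8 at 3.33 and 215 ± 10, FAM83G at 0 and 274 ± 38.1, MAN1A1 at 0.379 and 139 ± 1.67 and CA8 at 0.421 and 108 ± 13.1. LINC03018 stood at 0.421 and 149 ± 2.35, LINC02193 at 2.69 and 164 ± 2.43 and PRODHLP at 2.44 and 151 ± 24.3. In the other direction ICAM3 (chromosome 19, 10333776 to 10339823), a leukocyte adhesion gene, stood at 1539 ± 43.6 in the LacZ clone and 0.44 in the AML1/ETO clone, and PRDX2 (chromosome 19, 12796820 to 12801859), a peroxide scavenger gene, at 2041 ± 43.2 and 4.33 ± 0.10. ZFAND1 (649 ± 5.95), ASPH (578 ± 39.5), DNAJC15 (379.8 ± 37), RIPK2 (205 ± 3.56), TES (185 ± 12.2) and the death receptor gene TNFRSF10A (148 ± 7.21) with its neighbour TNFRSF10A-DT (128 ± 0.489) were read in the LacZ clone and had 0 reads in the AML1/ETO clone with ethanol. KCNAB1 stood at 434 ± 40.1 and 1.5. RUNX1 was lower in the AML1/ETO clone (-0.65, adjusted p = 0.0153), a call lost without LacZ_EtOH replicate 1 (-0.52), AE_EtOH replicate 1 or AE_EtOH replicate 2 (-0.65 in both).

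Of 6 tested MHC class II genes, which present antigen, 5 were higher in the AML1/ETO clone and 0 lower (median 1.45, adjusted p = 0.000494; adjusted p = 0.304 with an estimated correlation). HLA-DRA stood at 2.82 ± 0.776 and 136 ± 4.21, CD74 at 497 ± 6.61 and 1184 ± 33.7 and CIITA at 92.1 ± 31.4 and 361 ± 10.3. Of 30 interferon-stimulated genes 15 were higher and 2 lower (median 0.42, adjusted p = 0.0154; adjusted p = 0.304 with an estimated correlation), with SAMD9L at 96.8 ± 2.3 and 186 ± 9.31. Of 26 MYC and ribosome biogenesis genes 12 were lower and 0 higher (median -0.31, adjusted p = 0.000105; adjusted p = 0.304 with an estimated correlation), with BOP1 at 2524 ± 49 and 1221 ± 53.9. Of 10 LXR target genes 5 were lower and 0 higher (median -0.69, adjusted p = 0.00192; adjusted p = 0.506 with an estimated correlation), with SCD, a fatty acid desaturase gene, at 57258 ± 2387 and 31769.9 ± 194 and MYLIP at 1441 ± 13.2 and 739 ± 52. Of 32 ribosomal protein genes 2 were lower and 0 higher (median -0.16, adjusted p = 0.00840; adjusted p = 0.847 with an estimated correlation). Of 29 S phase genes 6 were higher and 2 lower (median 0.18, adjusted p = 0.0336; adjusted p = 0.305 with an estimated correlation), with CCNE1, which encodes cyclin E1, at 274 ± 2.55 and 473 ± 18.6. Of 17 cell cycle inhibitors 5 were higher and 0 lower (median 0.20, adjusted p = 0.0336; adjusted p = 0.466 with an estimated correlation), with CDKN2C at 1209.8 ± 56.7 and 2468 ± 2.54.

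By the limma test 3479 genes differed between the clones under ethanol, 1812 higher and 1667 lower in the AML1/ETO clone, with 395 and 434 at least 2-fold. Adjusted over the list alone, the members called higher and lower were 5 and 0 for MHC class II, 15 and 5 for interferon-stimulated genes, 0 and 13 for MYC, 0 and 7 for LXR, 0 and 2 for ribosomal proteins, 8 and 2 for S phase and 5 and 0 for cell cycle inhibitors. The count was 1939, 1940, 1636 and 1645 without LacZ_EtOH replicate 1, LacZ_EtOH replicate 2, AE_EtOH replicate 1 and AE_EtOH replicate 2. List calls ended for ribosomal proteins without LacZ_EtOH replicate 2 (adjusted p = 0.246), for S phase without LacZ_EtOH replicate 1 (0.0562) or AE_EtOH replicate 1 (0.0642), and for cell cycle inhibitors without LacZ_EtOH replicate 1 (0.0537) or AE_EtOH replicate 2 (0.0864). The last 2 also ended among genes with a mean of at least 50 (0.0698 and 0.0778), with equal totals (0.0608 and 0.0565) and after quantile normalization (0.116 and 0.0643).

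Under ponasterone A the series also sets the AML1/ETO clone against the LacZ clone. Here too AML1/ETO and other differences between the clones cannot be told apart. By the limma test 5739 genes differed, 3072 higher and 2667 lower in the AML1/ETO clone, with 859 and 691 at least 2-fold. CXCL10 was higher there by 10.07 (adjusted p = 3.09e-06), CDKN1A by 3.53, OAS1 by 3.85, PLIN2 by 2.88 and CD36 by 1.68 on the log2 scale. DEFB1 was higher by 9.72, and AZU1 (-1.21), INSIG1 (-0.84), PDYN (-2.55) and PRDX2 (-8.78) were lower. RPS16 (-0.81, adjusted p = 0.0643), RPLP1 (-0.68, adjusted p = 0.0638) and RUNX1 (0.43, adjusted p = 0.0569) did not pass.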

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

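Among the tests of this part, those of GC content and of a gradient for the LacZ calls, and those of GC content and of the ribosomal protein class for RPS16 and RPLP1, were chosen only after the result was seen, as were the LacZ values of the pseudogene test, the GC correction itself and, in the deletion test, the median over genes and its margin of 1 standard error.

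Results stand here because the 2 clones answered ponasterone A differently by the interaction test. That test called 1546 genes. The log2 differences (AML1/ETO clone minus LacZ clone) were 10.28 for PPIAP46, 8.55 for TM4SF1, 7.71 for CXCL10, 7.64 for CXCL11, 7.56 for CYP2B7P, 6.97 for CYP11A1, 6.83 for CLRN3, 6.27 for IL7R, 5.94 for SPOCD1 and 5.89 for ZNF117, where those of genes near 0 reads under ethanol depend on the added 1. They were -2.96 for IGFL2-AS1, -2.65 for PDYN, -2.15 for HLA-DRA, -2.14 for C2orf72 (-0.70 and not passing with an added 5), -2.06 for GNRHR2, -2.05 for LINC02908, -2.01 for PTPN22, -1.95 for LRRC2, -1.85 for FAM9C and -1.84 for BPI, and 1.08 for RUNX1. List medians of the difference were 1.84 for interferon-stimulated genes, 0.81 for monocyte genes, 0.76 for inflammatory genes, 0.31 for apoptosis regulators, 0.30 for PPAR targets, -0.14 for mitosis, -0.32 for primary granules and -0.32 for cholesterol synthesis.

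In the LacZ clone, which lacks AML1/ETO, 4708 genes were called under ponasterone A, and 1 without LacZ_EtOH replicate 1. Against the GC trend of the libraries as the whole cause stands that 93.7% of the number was left after GC correction (4412 genes, of which 3338 were shared with the 4708). A gradient that runs through the LacZ libraries and also parts replicates stays open: across genes the difference between the ethanol replicates correlated at 0.197, and that between the ponasterone A replicates at 0.324, with the fold change in the AML1/ETO clone, measured on other libraries. With the LacZ fold change itself these correlations were 0.386 and 0.584, which share libraries. A response to the inducer and such a gradient cannot be told apart here, because 2 samples per group leave the order along it confounded with treatment, and the response to the inducer itself was not tested separately.

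RPS16 and RPLP1 fell in both clones. RPS16 read 16978 and 7558 (LacZ, ethanol), 1283 and 861 (LacZ, ponasterone A), 10161 and 8563 (AML1/ETO, ethanol) and 636 and 564 (AML1/ETO, ponasterone A). The 11 annotated pseudogenes changed by -0.0377% (AML1/ETO clone) and -0.00121% (LacZ clone) of the value that RPS16 and RPLP1 lost together. The pooled loss therefore did not reappear on these copies, and RPS16 was not tested on its own. Reads shared with the copies stay open as a cause. Reads with several positions may have been left uncounted, as their handling is not given. The GC trend is excluded as the whole cause, since at least 97.5% (AML1/ETO) and 98.0% (LacZ) of each log2 fold change was left after correction, and a loss of the class is excluded, as the other 31 listed ribosomal protein genes had medians of 0.303 (AML1/ETO, 9 higher, 1 lower) and 0.448 (LacZ, 21 higher, 1 lower). A change shared by both clones may be an effect of the inducer on these transcripts or on how their reads were assigned, and neither was tested.

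Besides RUNX1T1, the ETO part of the fusion, 13 genes stayed under 10 in every library of 1 clone and reached at least 200 in every library of the other, 4 in the AML1/ETO clone and 9 in the LacZ clone. Loss of the surrounding region could explain such genes, and would lower those neighbours within 500 kb that it covers. Over the 12 genes with tested neighbours (140 neighbours), the median of the gene medians was 0.249 toward the clone with reads. It lay under the bound of 0.5 set beforehand, and the standard error of the mean of these medians was 0.103. This argues against loss of most of the neighbours as the common cause for the set. A loss that covers a minority of the neighbours would leave these medians near 0. Neighbours that were themselves one-clone genes were left out. Shorter regional losses therefore stay open. Loss of most of the neighbours stays open for single genes, as the medians of F13A1 (0.757), ZFAND1 (0.662) and RIPK2 (0.806) lay above that bound. DNAJC15 had no tested neighbours. Deletions of the gene alone and clone-specific silencing were not tested.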

How the results depend on the processing

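Among the alternatives, GC correction, GC and length correction, and the joint removal of LacZ_EtOH replicate 1 and LacZ_PonA replicate 2 (the end libraries) were tests chosen only after the result was seen. For named genes and lists other than RUNX1T1 and RUNX1 the alternatives gave 4861 results of the same direction and side of the threshold, 310 that no longer passed, and 0 reversed. A list that turned direction without passing was counted among the 310, so the lists among them need not all keep their direction. For RUNX1T1 and RUNX1 these counts were 78, 31 and 0. A lone sample left after removing its replicate is assumed to vary like the other groups. With 2 samples per group and 21696799 to 33082585 reads per library, 1.5-fold changes were recovered in 44.8% of simulated cases on induction and 8.96% for the difference, so genes not called include changes of that size.

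A minimum log2 fold change of 1 gave 1771 genes (induction), 391 (LacZ), 646 (difference), 829 (clones, ethanol) and 1550 (clones, ponasterone A), by construction. With only the groups compared LacZ gave 0 genes, with fewer samples behind the spread. In that setting induction gave 8298, against 7589 in the main test, and clones under ethanol 4984, against 3479. Fewer samples alone therefore do not account for the LacZ loss. The LacZ groups also spread more between replicates, with chi-squared per degree of freedom of 17.1 and 28.8, against 9.78 and 12.9 for AML1/ETO. The main model shares 1 spread per gene over both clones, so its LacZ p-values draw on the AML1/ETO libraries. How much of the loss this explains was not tested. GC and length correction gave 2629 for the difference, and the cause was not tested. With an estimated correlation 0 lists passed on induction, 0 in LacZ, 1 for the difference and 0 between clones under ethanol, a test that allows for correlated members. By fry, which asks another question, 15 passed on induction, 5 in LacZ, 11 for the difference and 14 between clones under ethanol. None of the 7 lists called in LacZ passed by fry (0.0708 to 0.137), nor did methyltransferases (0.0747) and Polycomb (0.0914) on induction, mitosis for the difference (0.156) or ribosomal proteins under ethanol (0.248).

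The RUNX1T1 rise stood at 0.63 with an added 0.5, with no filter and with the replicate block, at 0.55 with equal totals and at 0.52 with GC correction, no longer passing. The RUNX1 fall in LacZ stood at -0.47 with no filter, the 2 groups only or the block, at -0.39 after quantile normalization, -0.27 after GC and length correction and -0.38 without the end libraries, where the RUNX1 difference was 1.00 and the clone difference under ethanol -0.52. None of these passed, and the cause was not tested.

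Leaving out 1 library gave 5010 (without AE_EtOH replicate 2) to 8518 genes on induction, 1 (without LacZ_EtOH replicate 1) to 6733 in LacZ, 637 (without AE_EtOH replicate 2) to 2366 (without LacZ_PonA replicate 1) for the difference, 1636 (without AE_EtOH replicate 1) to 4637 between clones under ethanol and 4051 to 5959 under ponasterone A. Lists passing ran from 7 to 10, 7 to 9, 7 to 12 and 5 to 8. RUNX1T1 ran from 0.40 to 0.87 (without AE_PonA replicates 2 and 1), and RUNX1 from 0.36 to 0.87 on induction, -0.60 to -0.33 in LacZ, 0.82 to 1.33 for the difference and -0.79 to -0.52 between clones. No label says that replicate numbers pair the samples. Deviations of equal numbers correlated across genes at 0.27 between the LacZ groups and at 0.04 between the AML1/ETO groups. Between groups of different clones they correlated at -0.04, -0.03, -0.19 and -0.27. The value of 0.27 leaves a pairing within the LacZ clone open, and it cannot be told apart from a gradient among those libraries. A replicate block gave 7149, 3952, 1175, 3016 and 5312 genes, an overlap of 2885 between the clones and 8, 7, 8 and 7 lists.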

Other observations

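Among the tests of this part, the lists of aryl hydrocarbon receptor targets and of interferon genes, the margin of 1 standard error in the receptor test, the correlations with the difference of the ponasterone A effects and the list tests between the clones under ponasterone A were chosen only after the result was seen.

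Between the clones under ethanol, stem and progenitor genes did not pass as a list (5 higher and 5 lower of 18, adjusted p = 0.835), nor did secondary and tertiary granule genes (5 higher and 2 lower of 11, adjusted p = 0.227). Some single genes passed. FLT3, a receptor gene of early progenitors, stood at 97 ± 3.35 in the LacZ clone and 3.89 ± 0.522 in the AML1/ETO clone, SOX4 at 1116 ± 64.9 and 2528 ± 186, MEIS1 at 4458 ± 22 and 7271 ± 29.8 and the granule collagenase gene MMP8 at 9.43 ± 3.8 and 121 ± 18.3. The laminin receptor gene ITGA6 stood at 9914 ± 354 and 34434 ± 117, in a list of integrins and adhesion genes with 8 higher and 2 lower of 22 (adjusted p = 0.0926), and CD4 at 2982 ± 123 and 1179.8 ± 45.2. Under ponasterone A 13 of 17 primary granule genes were lower and 1 higher in the AML1/ETO clone (median -0.97, adjusted p = 4.32e-06; adjusted p = 0.274 with an estimated correlation), and 25 of 30 interferon-stimulated genes were higher and 4 lower (median 2.15).

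On induction several lists held members that moved apart. Of 29 S phase genes 13 rose and 7 fell (adjusted p = 0.269), of 32 DNA repair genes 14 rose and 11 fell (0.781), of 22 integrin and adhesion genes 9 rose and 8 fell (0.787), of 26 hypoxia and glycolysis genes 7 rose and 9 fell (0.745) and of 27 stress response genes 6 rose and 7 fell (0.508). Among 24 corepressor and RUNX1 partner genes 6 rose and 8 fell (0.942), with RUNX2 rising from 226 ± 13.9 to 646 ± 68.7. HIF1A rose from 2843 ± 5.05 to 5913 ± 52, TRIB1 from 23.4 ± 2.99 to 279.9 ± 46.1 and FABP4 from 6.27 ± 0.161 to 527 ± 102. Interferon genes themselves were near 0: IFNB1 read 4.01 and 5.44 in the induced AML1/ETO clone (8 reads) against 3 reads in the other 6 libraries, and IFNL1 1.34 and 1.09.

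CYP1A1, a detoxifying cytochrome P450 gene (chromosome 15, 74719542 to 74725610) chosen after its values were seen, rose from 108 ± 12.1 to 4828 ± 97.8 in the AML1/ETO clone and stood at 95.7 ± 9.15 and 118 ± 10.3 in the LacZ clone (difference 5.18, adjusted p = 8.06e-07). Activity of the aryl hydrocarbon receptor may lie behind it. The median difference of the 5 other tested targets, TIPARP (0.12), AHRR (-0.49), NQO1 (0.47), NFE2L2 (0.12) and SLC7A5 (0.16), was 0.120. It lay under the bound set beforehand, 0.2. The standard error of the mean over these genes, which are not replicates, was 0.156. With that margin, added after the result was seen, the median lies too near the bound to exclude the receptor, so the hypothesis stays open. CYP1A2 read 8.02 and 8.71 in the induced AML1/ETO clone against 1 read elsewhere.

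CYP11A1, PPIAP46 and CYP1A1 lie close together on chromosome 15, so activation of the whole region could raise them. The 14 other tested genes within 500 kb of CYP11A1 had a median difference of -0.179, with 0 called higher and 1, ULK3, called lower. The tested genes of the region thus did not rise as a set. Genes with a mean under 10 were not tested, so activation of genes near 0 reads stays open. A rise of cytochrome P450 genes as a class could also account for CYP11A1, CYP1A1 and CYP2B7P. The 12 other tested P450 genes had a median difference of -0.0559, with 2 called higher and 0 lower, which excludes a rise of the tested P450 genes as a class. Those with a mean under 10 were not tested.

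RUNX1T1 was read in the uninduced AML1/ETO clone, so the clone difference under ethanol could reflect fusion already present. In that case the clone difference and the change on induction should run the same way across genes. From separate ethanol libraries their correlations were -0.0379 and -0.0517, and with the difference of the ponasterone A effects, which leaves out what the clones share, they ran from -0.0484 to -0.0290. Across genes the clone difference thus did not run with the change on induction. This cannot exclude an effect of the fusion under ethanol, because clone differences of other origin would hide a shared part. Such an effect stays open, also for interferon-stimulated genes. These were higher under ethanol (15 higher and 2 lower of 30, median 0.42) and rose on induction (22 rose and 3 fell, median 1.89).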
